A study of Saccharomyces cerevisiae with 27 samples.

How the data were processed

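Messenger RNA was measured on 27 Affymetrix Yeast Genome 2.0 arrays, each hybridised with biotin-labelled RNA from haploid budding yeast of the W303 background. Per the labels, cells grown on 2% raffinose were held in G2/M and shifted to a higher temperature, received galactose 30 min later and were collected after a further 90 min. Galactose turns on the HO endonuclease, which makes 1 double-strand break in strains that carry its recognition site. The labels give galactose for every group, so groups with and without a break are read here as different strains, and a response to the break is not separated from another difference between them. RNA was extracted after zymolase digestion for 1 h at 30 °C. The labels name chromosome VI for the break in the sample descriptions and chr.iv in a characteristic, and this conflict was not settled from the labels. The value table deposited by the authors holds log2 expression values that were summarised with RMA in R 2.9.2, per the submitters' processing notes. RMA corrects the background, quantile-normalizes the arrays that are processed together and summarises the probes of a probe set. The version of RMA and the arrays that entered each run were not given in the sources used here. No scanner files were used, so the log2 scale rests on RMA as named and on the range of the values, the centring of each column is unknown, and no direction had to be set because each array held 1 sample.

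The samples were grouped by their labels into wild type without a break (7 arrays), wild type with a break (6 arrays), scc2-4 without a break (7 arrays) and scc2-4 with a break (7 arrays). Each group spanned 2 experiments, which the labels number, with 3 arrays per group in experiment 1 and 3 or 4 in experiment 2. The labels call the replicates biological. Arrays are named here by experiment and replicate, so that 2_3 is replicate 3 of experiment 2. The precision is limited by the number of arrays. The replicate numbers were not used to pair arrays. The fits treat the arrays as independent, although some arrays of a group lay closer together than others. In wild type without a break the median absolute difference was 0.036 between 1_1 and 1_2 and 0.116 between 1_1 and 1_3. The standard errors and p-values do not allow for such closeness.

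Column medians in log2 units were 10.20, 10.19 and 10.20 for wild type without a break in experiment 1, 10.20, 10.20 and 10.22 for wild type with a break, 10.22, 10.22 and 10.22 for scc2-4 without a break, and 10.21, 10.22 and 10.20 for scc2-4 with a break. In experiment 2 they were 9.77, 9.79, 9.79 and 9.77 for wild type without a break, 9.78, 9.77 and 9.76 for wild type with a break, 10.02, 10.01, 10.04 and 10.02 for scc2-4 without a break, and 10.02, 10.02, 10.01 and 10.01 for scc2-4 with a break. The sorted values of any pair of arrays differed by a mean of 0.00818 to 0.0302 within the 12 arrays of experiment 1, within the 7 wild-type arrays of experiment 2 and within the 8 scc2-4 arrays of experiment 2, and by 0.147 to 0.425 between these 3 sets. They are called processing sets here. In experiment 2 genotype and processing set cannot be told apart. Both states of the break lay in every set.

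Of 5684 probe sets in the table used here, 5468 had 1 gene symbol in the probe table, 0 had several and 216 had none. Symbols were updated through the gene table of the R64 assembly, which was also used to find neighbouring genes. No coordinates are given, because no build is named in the sources. For the 34 genes with several probe sets the one with the highest mean was kept, which left 5434 genes. Unnamed probe sets were fitted apart and no gene was named from them.

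Before the data were examined, the groups, the model, the 5 comparisons, 41 gene lists, the rule for named genes and the first set of alternatives were fixed. The model held the 4 groups and experiment as an additive term over all 27 arrays, fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. The comparisons were scc2-4 against wild type without a break, the same with a break, break against no break in wild type, the same in scc2-4, and the difference of these last effects (interaction). Log2 changes are given with the standard error of the fit. Gene lists with at least 5 measured members (39 of 41) were tested with camera at a preset correlation between genes of 0.01, then with a correlation estimated per list, and with fry. List p-values were adjusted over the 39 lists. Counts of members are given over all genes tested and adjusted over the list alone.

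The named genes were the 12 largest rises and the 12 largest falls past the threshold with the same sign in both experiments, up to 4 members with the largest change of each list described, and 7 genes measured out of those fixed for every comparison (SCC2, SCC4, MCD1, HO, GAL1, RNR3 and HUG1). Some of the genes so chosen are left to the summary counts. GEX1, YLL066W-B, YLR156W, YLR157W-E and ASP3-1 were read by probe sets of a kind that matches several near-identical transcripts, so their values are uncertain as to which copy they measure.

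After the column distributions had been seen, a model with the processing set in place of experiment was added, and its values are printed beside those of the planned model under the name set block. With it the level of the genotype difference, averaged over the states of the break, rests on experiment 1. Its change with the break, like the break comparisons, uses all sets. A set-block value of a genotype comparison can therefore lie outside the values of both experiments. A split of each set by the first component of the deviations from the group means (71.0, 65.2 and 60.2% of the variance within the sets) was also added and is used in the closing section only, because such a term makes p-values too small. The other alternatives were centring or quantile-normalizing the arrays again, a filter on dim genes, all probe sets, no experiment term, each experiment alone, the compared groups alone, a trended robust variance model, array weights, a 1.5-fold minimum, a replicate block and leaving out each array. Single scores were tested with exact two-sided permutation of the break labels within genotype and experiment, which assumes no break effect in either genotype. For a difference of break effects, 9999 permutations of the residuals of the model without the interaction, within processing sets, were added after the results had been seen.

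The test was tried on simulated data for break against no break in wild type over 5434 genes. The planned model recovered 80% of the genes given a log2 change of 0.5 and 99% of those given 1, with 0 false calls, and the set block recovered 96% and 100% with 4 false calls. These data were drawn from the set-block fit, with noise independent between genes and arrays. They lack the structure of the real arrays within the sets, so they do not give error rates for the real arrays.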

Results

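The expression data cover wild-type yeast and the temperature-sensitive scc2-4 mutant, in which the loader that places cohesin on chromosomes is inactivated by heat, each with and without 1 HO-induced double-strand break in G2/M. The design asks how loss of Scc2 function changes transcription without a break and with one, how each genotype responds to the break, and whether the responses differ. The fits used 27 arrays, 6 or 7 per group. HO, the endonuclease, was measured at a mean of 13.5 log2 units over all arrays, a level exceeded by 1.90% of probe sets, and GAL1, the galactokinase induced by the same sugar, at 14.1. With the planned model and with the set block neither gene passed in any of the 5 comparisons, but the genotype differences passed in other settings. HO passed without a break in experiment 1 alone (0.16; limma adjusted p = 0.0486) and with a break when arrays were centred (−0.17; adjusted p = 0.0212) or quantile-normalized (−0.13; adjusted p = 0.0442). GAL1 passed without a break with centring (−0.11), quantile normalization (−0.056), array weights (0.079) and experiment 2 alone (0.088), and with a break with centring (−0.11) and experiment 2 alone (0.083). For HO the log2 difference between scc2-4 and wild type was 0.05 ± 0.04 (SE; 7 against 7 arrays; limma adjusted p = 0.27) without a break and −0.03 ± 0.04 (7 against 6; adjusted p = 0.586) with one (0.10 and 0.02 with the set block). For GAL1 these differences were 0.04 ± 0.03 (adjusted p = 0.223) and 0.03 ± 0.03 (adjusted p = 0.332), and −0.03 in both with the set block. SCC2 mRNA was lower in scc2-4 by a log2 change of −0.35 ± 0.03 without a break and −0.47 ± 0.04 with one (−0.36 and −0.48 with the set block). The mutation acts on the protein, so this level does not check the labels.

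Without a break 2532 of all 5434 genes were higher in scc2-4 and 1062 lower (1125 and 975 with the set block). Counts of list members are to be read against these shares. All 66 measured genes of the mitochondrial ribosome, which translates the proteins encoded by mitochondrial DNA, were higher in scc2-4 cells than in wild type (66 also adjusted over the list alone), with a median log2 change of 0.83. The camera test gave adjusted p = 4.91e-16 with the preset correlation and adjusted p = 0.682 with an estimated correlation (0.634 with the set block). MRPS8, MRPL1 and MRPL19 rose by 1.40 ± 0.18, 1.39 ± 0.20 and 1.34 ± 0.18 (SE, 7 against 7 arrays). The list median was 0.44 in experiment 1 and 1.17 in experiment 2, and 64 of 66 genes were higher with the set block (median 0.43, 66 adjusted over the list alone). Of 47 genes of respiration and the TCA cycle, 43 rose and 0 fell (44 and 0 adjusted over the list alone; median 0.31), and 21 rose with the set block (median 0.10). Adjusted p was 2.99e-06 for this list and adjusted p = 0.867 with an estimated correlation. ATP20, a subunit of ATP synthase, rose by 0.75 ± 0.10 (0.47 with the set block) and ACO1, aconitase, by 0.66 ± 0.08 (0.36).

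The largest rises without a break included the uncharacterised YCL021W-A with a log2 change of 2.27 ± 0.19 (4.82-fold; limma adjusted p = 1.72e-09; 1.54 with the set block). ARG1 and ARG3, enzymes of arginine synthesis, rose by 2.21 ± 0.28 and 2.12 ± 0.23 (1.23 and 1.43 with the set block). COX17 and COX10, which supply copper and haem A to cytochrome oxidase, rose by 1.76 ± 0.20 and 1.58 ± 0.19 (1.06 and 1.01). The mitochondrial tRNA modification gene MTO1 rose by 1.57 ± 0.20 (0.90) and MLS1, malate synthase, by 1.59 ± 0.18 (0.99). The isomaltase gene IMA5 rose by 1.59 ± 0.14 (1.23). AQY2, an aquaporin gene, its neighbour YLL053C and PHO92 rose by 2.21 ± 0.39, 1.66 ± 0.30 and 1.56 ± 0.27, but by 0.63, 0.46 and 0.63 with the set block. Of 48 Gcn4 targets in amino acid synthesis 42 rose and 0 fell (42 and 1 adjusted over the list alone; median 0.40), whereas 14 rose and 7 fell with the set block (median 0.02). Among them ARG4 rose by 1.22 ± 0.20 (0.43 with the set block) and HIS1, of histidine synthesis, by 0.95 ± 0.17 (0.29). The list gave adjusted p = 0.000421, adjusted p = 0.95 with an estimated correlation, and adjusted p = 0.35 with the set block.

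Of 29 genes of iron uptake 21 rose and 3 fell in scc2-4 without a break (21 and 3 adjusted over the list alone), and 11 rose and 3 fell with the set block. The list median was 0.43 over all arrays, 0.10 in experiment 1 and 0.68 in experiment 2, with adjusted p = 0.0224 and adjusted p = 0.852 with an estimated correlation. The ferric reductase genes FRE2 and FRE3 rose by 1.51 ± 0.09 and 1.34 ± 0.20 (1.42 and 1.61 with the set block), and FRE7, a cupric reductase gene, by 1.74 ± 0.21 (1.31). FTR1, the iron permease, and ARN2, a siderophore transporter, rose by 1.40 ± 0.26 and 1.27 ± 0.18 (0.43 and 0.70).

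Of 36 proteasome genes 19 fell and 0 rose without a break (19 and 0 adjusted over the list alone; median −0.13), and 35 fell with the set block (median −0.24). The median was −0.25 in experiment 1 and −0.03 in experiment 2. ECM29 and RPN3, a proteasome adaptor and a lid subunit, had log2 changes of −0.49 ± 0.06 and −0.39 ± 0.05, and RPT4, a base ATPase, of −0.29 ± 0.03. Adjusted p for the list was 1.24e-09 and adjusted p = 0.617 with an estimated correlation, and the latter was 0.025 with the set block. Of 20 homologous recombination genes 7 fell and 3 rose (the same counts adjusted over the list alone), and 10 fell and 2 rose with the set block. RAD54 and RDH54, which encode DNA translocases of strand exchange, had changes of −0.68 ± 0.12 and −0.46 ± 0.06, TOP3, a topoisomerase gene, of −0.43 ± 0.06, and the helicase gene MPH1 of 0.37 ± 0.04. Adjusted p was 0.025 for the list and adjusted p = 0.682 with an estimated correlation.

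Among 15 cohesin genes without a break, 8 fell and 5 rose (8 and 5 adjusted over the list alone), and 6 fell and 2 rose with the set block. SMC1 and SMC3, the core subunits of the ring, had log2 changes of −0.41 ± 0.05 and −0.35 ± 0.07 (−0.26 and −0.53 with the set block), and REC8, the meiotic kleisin, of −0.48 ± 0.09 (−0.20; adjusted p = 0.0611). The list gave adjusted p = 0.0333 and adjusted p = 0.615 with an estimated correlation. MCD1, the mitotic kleisin, was higher by 0.33 ± 0.09 (adjusted p = 0.00222) over all arrays, with −0.03 in experiment 1, 0.61 in experiment 2 and 0.04 with the set block (adjusted p = 0.659). SCC4, the partner of Scc2 in the loader, was lower by −0.15 ± 0.06 (adjusted p = 0.0283), with 0.04 in experiment 1 and 0.01 with the set block (adjusted p = 0.92). The SCC4 call ended on leaving out wild type 2_3 (−0.12) or 2_4 (−0.14) or scc2-4 2_1 (−0.13), 2_3 (−0.12) or 2_4 (−0.13), all without a break. RNR3, an inducible ribonucleotide reductase subunit, was higher by 0.45 ± 0.13 (adjusted p = 0.00506), with −0.15 in experiment 1 and 0.02 with the set block (adjusted p = 0.924). HUG1, an inhibitor of the same enzyme, was at −0.04 ± 0.09 (adjusted p = 0.683).

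Of 36 targets of the stress factors Msn2 and Msn4 26 fell and 0 rose without a break over all arrays (26 and 0 adjusted over the list alone; median −0.42), but the median was 0.04 in experiment 1 and −0.80 in experiment 2, and with the set block 0 fell and 2 rose. For the list as a group adjusted p was 1.93e-09, adjusted p = 0.682 with an estimated correlation and adjusted p = 0.956 with the set block. Glycogen synthase GSY1, the catalase CTT1 and the aldehyde dehydrogenase ALD3 had changes of −1.5 ± 0.32, −1.29 ± 0.27 and −1.46 ± 0.36, against −0.28, −0.29 and −0.03 with the set block (adjusted p = 0.193, 0.108 and 0.883). The 95 ribosome biogenesis genes had a median of 0.10 while camera pointed down (adjusted p = 0.36; adjusted p = 0.95 with an estimated correlation), with 11 higher and 8 lower (6 and 3 adjusted over the list alone). With the set block 44 fell and 0 rose (48 and 0 adjusted over the list alone; median −0.20; adjusted p = 1.26e-08; adjusted p = 0.735 with an estimated correlation). NIP7 and RRP36, ribosome assembly factors, were higher by 0.69 ± 0.21 and 0.55 ± 0.17 over all arrays and at −0.02 each with the set block.

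The largest falls without a break were led by MGA1, related to heat shock factor, at −2.12 ± 0.26 (4.36-fold; adjusted p = 4.86e-07; −1.30 with the set block). GEX1, a glutathione exchanger, was at −1.39 ± 0.09 (−1.51) and the uncharacterised YIR018C-A at −1.47 ± 0.22 (−0.63). The kinase gene VHS1, the sterol regulator SUT1 and MIH1, the phosphatase that activates the mitotic kinase, were at −1.70 ± 0.33, −1.37 ± 0.27 and −1.35 ± 0.25 (−0.41, −0.31 and −0.43 with the set block). For SLZ1, TKL2, PHM7, SOL4 and YNL195C the planned changes were −1.84 ± 0.38, −1.70 ± 0.40, −1.62 ± 0.40, −1.44 ± 0.31 and −1.38 ± 0.32, and none of these 5 passed with the set block (−0.40, −0.17, −0.13, −0.28 and −0.17; adjusted p = 0.135, 0.503, 0.671, 0.217 and 0.467). In all, 3594 of 5434 genes passed without a break, 2532 higher and 1062 lower (70.5% higher; median of all genes 0.13). The set block gave 2100, 1125 higher and 975 lower (53.6% higher), and 1342 genes passed in both. Experiment 1 alone gave 1569 genes (839 higher and 730 lower) and experiment 2 alone 4613 (3321 and 1292). The effect of experiment on the genotype difference passed for 4118 genes, and 73.5% of the 3594 had the same sign in both experiments. Over genes, which are not independent replicates, r between the experiments was 0.35.

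**Figure D1:**
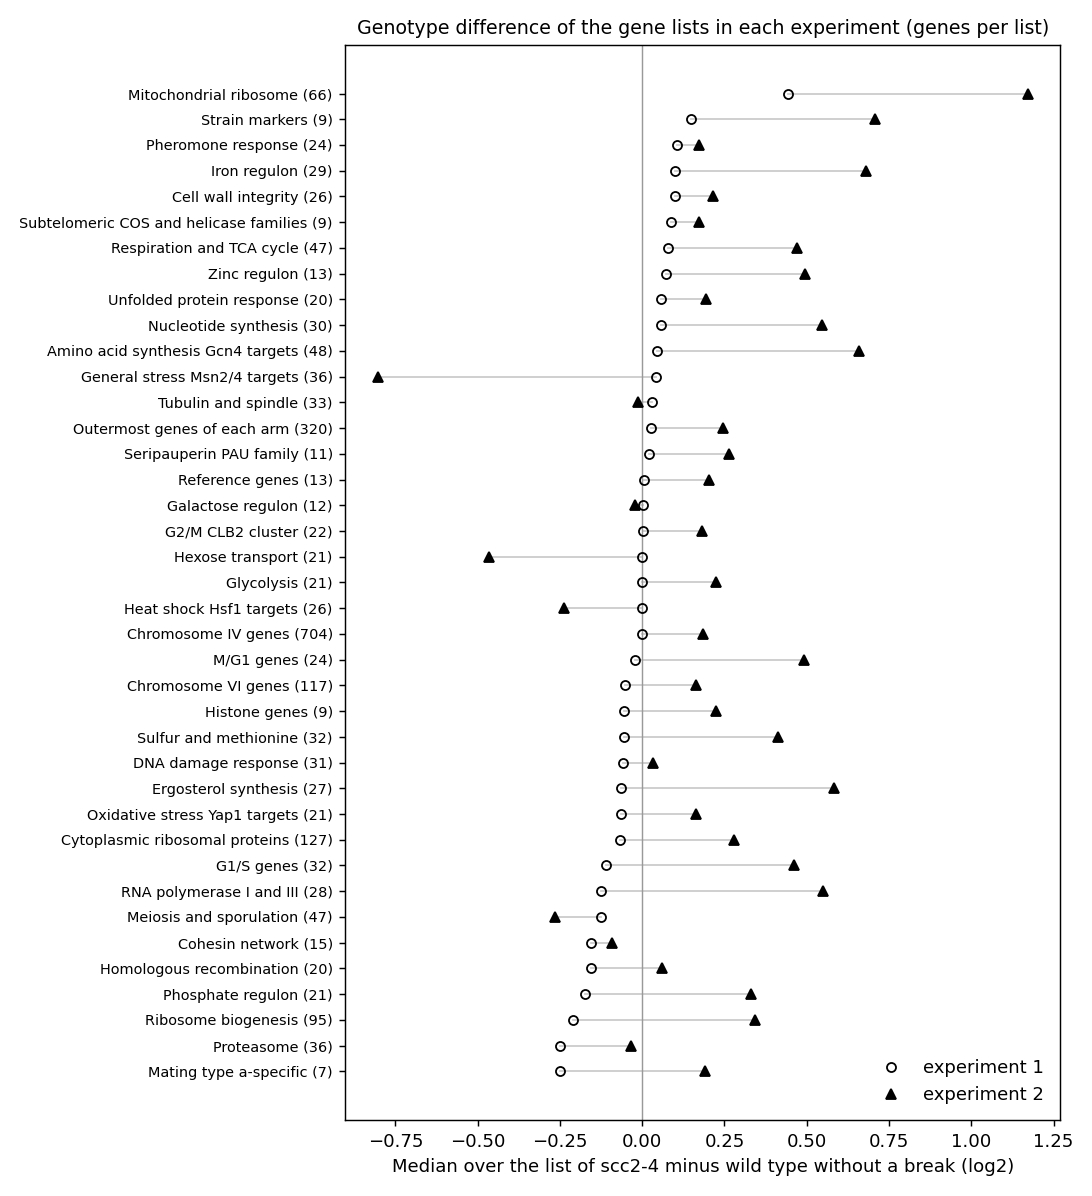
Median log2 difference between scc2-4 and wild type without a break over each gene list, in experiment 1 (open circles) and experiment 2 (filled triangles), with the number of genes per list in parentheses. The mitochondrial ribosome lies above 0 in both (0.44 and 1.17), and the Msn2/4 targets lie at 0.04 and −0.80.

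With a break 2340 of all 5434 genes were higher in scc2-4 and 1016 lower (1212 and 1106 with the set block). In this comparison 16 of 31 genes of the DNA damage response were lower in scc2-4 than in wild type and 1 was higher (16 and 1 adjusted over the list alone; median −0.25), with a median of −0.24 in experiment 1 and −0.21 in experiment 2, and 19 lower with the set block. HUG1 was lower by −1.34 ± 0.09 (SE, 7 against 6 arrays; 2.53-fold; limma adjusted p = 8.1e-11), with −1.28 in experiment 1 and −1.41 in experiment 2. PLM2, a damage-induced gene whose protein has a forkhead-associated domain, was lower by −0.85 ± 0.14 (−0.96 with the set block). RAD54 was lower by −0.82 ± 0.12 (−0.44) and PCL5, a cyclin gene that controls Gcn4 turnover, by −0.81 ± 0.14 (−0.30). The list gave adjusted p = 1.21e-06 and adjusted p = 0.11 with an estimated correlation. RNR3 was at −0.10 ± 0.14 (adjusted p = 0.522) over all arrays and at −0.51 with the set block (adjusted p = 0.00027), with −0.35 in experiment 1 and 0.08 in experiment 2. The set-block value lies outside both because it also takes in the difference of the break effects from experiment 2.

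Of 20 homologous recombination genes 10 were lower and 3 higher in scc2-4 with a break (the same counts adjusted over the list alone), and 13 were lower with the set block. RDH54 and RAD52, which mediates strand exchange, were lower by −0.61 ± 0.06 and −0.54 ± 0.06 (−0.53 and −0.71 with the set block), and the end-resection gene SAE2 by −0.58 ± 0.10 (−0.30). This list gave adjusted p = 0.00105 and adjusted p = 0.359 with an estimated correlation. Of 15 cohesin genes 6 were lower and 4 higher (6 and 4 adjusted over the list alone). SMC1, SMC3 and IRR1, subunits of the complex, were lower by −0.68 ± 0.06, −0.58 ± 0.07 and −0.45 ± 0.07 (−0.54, −0.74 and −0.33). As a group the list had adjusted p of 0.0135, adjusted p = 0.308 with an estimated correlation and adjusted p = 0.0502 with the set block. MCD1 was at 0.14 ± 0.09 (adjusted p = 0.195) and SCC4 at −0.13 ± 0.06 (adjusted p = 0.0651), but at −0.14 and 0.02 with the set block (adjusted p = 0.0848 and 0.828). The SCC4 value passed in 3 of the 27 fits that left out 1 array, in which it ranged from −0.16 to −0.11.

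With a break, too, all 66 mitochondrial ribosome genes were higher in scc2-4 (66 adjusted over the list alone; 66 with the set block), with medians of 0.42 in experiment 1 and 1.18 in experiment 2. The list gave adjusted p = 5.01e-16 and adjusted p = 0.782 with an estimated correlation. RSM26 and MRPL32 were higher by 1.39 ± 0.21 and 1.38 ± 0.19 (0.69 and 0.81 with the set block). Of 47 respiration and TCA cycle genes 44 were higher and 0 lower (44 and 0 adjusted over the list alone), among them KGD1, of the α-ketoglutarate dehydrogenase, at 0.58 ± 0.06 (0.40), with adjusted p = 4.41e-07 for the list and adjusted p = 0.858 with an estimated correlation. Of 36 proteasome genes 21 were lower and 0 higher (21 and 0 adjusted over the list alone; 34 lower with the set block), with ECM29 at −0.61 ± 0.06 and RPT4 at −0.32 ± 0.03. That list gave adjusted p = 5.17e-10, and adjusted p = 0.381 with an estimated correlation (0.0414 with the set block). Of 24 M/G1 genes 19 were higher and 2 lower (19 and 2 adjusted over the list alone; 10 and 3 with the set block). The daughter-cell glucanase DSE4 and the regulator TEC1 were higher by 1.35 ± 0.24 and 1.10 ± 0.10 (0.50 and 0.76), and ASH1, a daughter-specific repressor, by 0.81 ± 0.16 (0.28). Adjusted p was 0.0147 for this list, adjusted p = 0.858 with an estimated correlation and 0.119 with the set block.

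The largest genotype differences with a break included FRE2 at 1.63 ± 0.09 (3.09-fold; adjusted p = 3.34e-12; 1.54 with the set block), YCL021W-A at 2.14 ± 0.20 (1.46) and FRE7 at 1.73 ± 0.21 (1.33). ARG1 and ARG3 were higher by 1.75 ± 0.30 and 1.72 ± 0.24 (0.83 and 1.08). YLL066W-B, from a subtelomeric repeat family, was lower by −2.19 ± 0.08 (4.56-fold; adjusted p = 7.45e-17; −2.30 with the set block), but at −0.42 with the set block by another probe set. MGA1, GEX1, the pyridoxine-related SNO1 and the Rab GTPase gene YPT53 were lower by −1.92 ± 0.27, −1.52 ± 0.09, −1.43 ± 0.21 and −1.63 ± 0.28 (−1.16, −1.64, −1.16 and −0.75). FDH1, formate dehydrogenase, was at 1.5 ± 0.39 over all arrays and at 0.86 with the set block (adjusted p = 0.124). GRE1, TKL2 and SPG1 were at −1.56 ± 0.43, −1.61 ± 0.41 and −1.48 ± 0.39 over all arrays and at −0.05, −0.18 and −0.18 with the set block (adjusted p = 0.861, 0.441 and 0.505). In all, 3356 genes passed, 2340 higher and 1016 lower (69.7% higher; median of all genes 0.12). The set block gave 2318, 1212 higher and 1106 lower (52.3% higher), with 1510 genes passing in both. Experiment 1 alone gave 1702 (915 higher and 787 lower) and experiment 2 alone 4500 (3197 and 1303), and 84.0% of the 3356 had the same sign in both. The number of gene lists past the threshold, 11 without a break and 12 with one, was no larger than in many other splits of the arrays, so the lists are read here by their members.

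In wild type 10 of 31 genes of the DNA damage response rose with a break and 0 fell (13 and 0 adjusted over the list alone; median 0.18), between groups that are read here as different strains. Adjusted p was 1.11e-18 for this list and adjusted p = 0.000768 with an estimated correlation. HUG1 rose by 2.67 ± 0.09 (SE, 6 against 7 arrays; 6.36-fold; limma adjusted p = 8.03e-17), from a mean of 7.34 to 9.82 in experiment 1 and from 7.02 to 9.85 in experiment 2. PLM2 rose by 1.69 ± 0.14, RNR3 by 1.15 ± 0.14 (adjusted p = 6.2e-06), and RNR1 and RNR2, the constitutive reductase subunits, by 0.69 ± 0.15 (adjusted p = 0.0101) and 0.59 ± 0.08. DUN1, the checkpoint kinase that controls ribonucleotide reductase, rose by 0.56 ± 0.04, and DIN7, a damage-induced nuclease gene, by 0.59 ± 0.07. ULI1, a gene of chromosome VI linked to the unfolded protein response, rose by 1.75 ± 0.09 (3.36-fold; adjusted p = 2.42e-13). FRD1, a fumarate reductase gene, the zinc-finger gene YPR015C, the silencing gene ESC8 and YLL066W-B rose by 0.67 ± 0.11, 0.67 ± 0.10, 0.58 ± 0.05 and 0.75 ± 0.08, but another probe set of YLL066W-B was at 0.23 (set block). The median of the DNA damage response list was 0.09 in experiment 1 and 0.22 in experiment 2, and 14 of its genes rose with the set block.

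A few genes of cohesion and recombination rose in wild type after the break. Of 15 cohesin genes 4 rose and 0 fell (7 and 2 adjusted over the list alone), namely IRR1 by 0.43 ± 0.07, PDS5, a regulator of the ring, by 0.42 ± 0.05, SMC1 by 0.33 ± 0.06 and PDS1, securin, by 0.29 ± 0.06. Adjusted p for the list was 0.000182 and adjusted p = 0.0391 with an estimated correlation (0.115 with the set block). MCD1 was at 0.33 ± 0.09 (adjusted p = 0.0566) and passed with the set block (0.31; adjusted p = 0.000204). Of 20 recombination genes 2 rose and 0 fell (8 and 0 adjusted over the list alone), RAD52 by 0.27 ± 0.06 and the helicase gene SRS2 by 0.22 ± 0.04. That list gave adjusted p = 3.04e-06 and adjusted p = 0.0891 with an estimated correlation. Of 32 G1/S genes 6 rose and 0 fell (15 and 0 adjusted over the list alone), among them RNR1, SMC1 and the histone chaperone gene ASF1 at 0.36 ± 0.07, with adjusted p = 2.22e-07 and adjusted p = 0.333 with an estimated correlation.

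A few genes expressed around mitosis and cell separation fell in wild type after the break. Of the 22 genes of the G2/M CLB2 cluster 5 fell and 0 rose (10 and 0 adjusted over the list alone; median −0.18), including HOF1, of cytokinesis, at −0.37 ± 0.07, the mitotic exit kinase DBF2 at −0.28 ± 0.04 and the bud-site gene BUD4 at −0.27 ± 0.05. The list gave adjusted p = 1.02e-12 and adjusted p = 0.0391 with an estimated correlation. Of 24 M/G1 genes 2 fell, DSE1, of daughter cell separation, at −0.55 ± 0.09 and the chitinase CTS1 at −0.27 ± 0.06 (8 lower and 1 higher adjusted over the list alone), and 16 fell with the set block. This list gave adjusted p = 2.7e-07 and adjusted p = 0.333 with an estimated correlation (0.0123 with the set block). Other falls were IRC8 at −0.36 ± 0.05, FRM2 at −0.35 ± 0.07, the splicing gene SAD1 at −0.31 ± 0.05, YPR078C at −0.32 ± 0.07 and the sporulation septin SPR3 at −0.30 ± 0.05. No proteasome or Msn2/4 target gene passed on its own with limma. Of 36 proteasome genes 0 passed (14 higher at an unadjusted p under 0.05; 4 higher adjusted over the list alone; 16 with the set block), with a median of 0.08, adjusted p = 2e-08 and adjusted p = 0.333 with an estimated correlation. Of 36 Msn2/4 targets 0 passed (3 higher at an unadjusted p under 0.05; 0 adjusted over the list alone; 7 higher with the set block), with a median of 0.05, adjusted p = 0.0233 and adjusted p = 0.897 with an estimated correlation.

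Of the 10 measured genes next to ULI1 on the right arm of chromosome VI 5 fell and 0 rose in wild type with the break (8 and 0 with the set block). CDC14, the phosphatase of mitotic exit, fell with a log2 change of −0.68 ± 0.08 (1.6-fold; adjusted p = 2.34e-06), HIS2, of histidine synthesis, with −0.53 ± 0.10 (adjusted p = 0.00412), the arrestin-like gene ROG3 with −0.43 ± 0.08 (adjusted p = 0.00307) and MET10, of sulfate assimilation, with −0.29 ± 0.05 (adjusted p = 0.00224). The 5 measured genes on each side of ULI1, in the gene order of the R64 assembly, had a mean change of −0.32 ± 0.03 (exact two-sided permutation p = 0.00143 over 700 splits, the smallest they allow). This window of 10 genes, chosen after the values were seen, ranked 3 by size among 5274 windows of the genome. Of 117 genes of chromosome VI 9 fell and 2 rose (14 and 4 adjusted over the list alone), with adjusted p = 0.000343 and adjusted p = 0.333 with an estimated correlation (0.0293 with the set block). In all 103 genes passed in wild type, 68 higher and 35 lower, and all 103 were among the 736 that passed with the set block (430 higher and 306 lower). The count was 22 in experiment 1 alone, 1273 in experiment 2 alone (589 higher and 684 lower) and 165 without wild type without a break 1_2. The number of lists past the threshold, 16, was reached by 8 of 100 splits of the arrays.

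**Figure D2:**
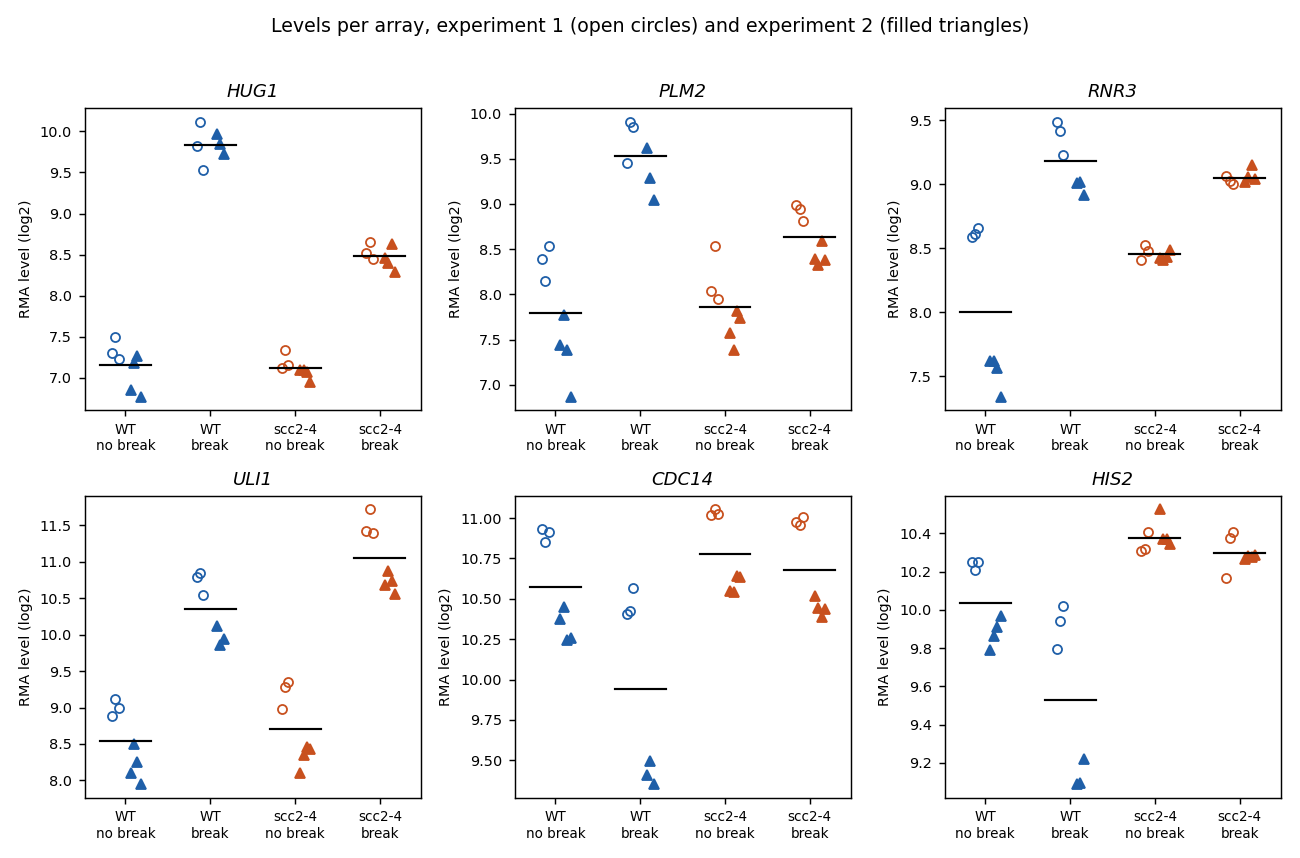
RMA log2 level per array of 6 genes in the 4 groups (open circles experiment 1, filled triangles experiment 2, line at the group mean). HUG1 lies near 9.82 and 9.85 in wild type with a break and near 8.54 and 8.44 in scc2-4 with a break.

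Between the scc2-4 strains with and without a break the largest rise was of ULI1, by 2.35 ± 0.08 (SE, 7 against 7 arrays; 5.1-fold; limma adjusted p = 1.62e-16). HUG1 rose by 1.37 ± 0.09 (2.59-fold; adjusted p = 5.9e-11), PLM2 by 0.77 ± 0.13 (adjusted p = 0.00155), DUN1 by 0.32 ± 0.04 and RNR3 by 0.60 ± 0.13 (adjusted p = 0.0269). The RNR3 call ended on leaving out scc2-4 without a break 1_1 (0.55), 1_2 (0.57) or 1_3 (0.57), or scc2-4 with a break 2_1 (0.58), 2_2 (0.57), 2_3 (0.55) or 2_4 (0.57), with adjusted p up to 0.0759. With the set block RNR3 kept its call in every such fit. Of 31 DNA damage response genes 4 rose and 0 fell (8 and 0 adjusted over the list alone; median 0.11), with adjusted p = 3.8e-09 and adjusted p = 0.0502 with an estimated correlation. The list median was 0.03 in experiment 1 and 0.17 in experiment 2. SLF1, an RNA-binding protein gene of copper homeostasis, rose by 0.71 ± 0.08, YPR015C by 0.52 ± 0.10, ECO1, the cohesin acetyltransferase, by 0.35 ± 0.06 and DIF1, which controls import of ribonucleotide reductase, by 0.34 ± 0.06. YLR156W, YLR157W-E and ASP3-1, the asparaginase gene, lie in the repeated region beside the ribosomal DNA and rose by 1.35 ± 0.19, 1.22 ± 0.14 and 0.40 ± 0.03. Another probe set of YLR157W-E, at a mean level of 3.94, was at 0.036.

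In scc2-4 with a break the uncharacterised YIR042C was lower, at −1.61 ± 0.14 (3.05-fold; adjusted p = 2.3e-08). YLL066W-B was at −1.61 ± 0.07 by a probe set shared with similar transcripts and at −0.08 by another probe set of the gene. Changes of such single genes are not separated here from other differences between the strains. COS8, of a subtelomeric membrane protein family, was at −0.56 ± 0.08, YER187W at −0.42 ± 0.06 and CMR2 at −0.25 ± 0.05. Of 48 Gcn4 targets 3 fell and 0 rose (11 and 0 adjusted over the list alone; median −0.12; 21 lower with the set block), among them ARO1, of aromatic amino acid synthesis, at −0.33 ± 0.06 and ARO3 at −0.19 ± 0.03. For the list as a group adjusted p was 2.58e-11 and adjusted p = 0.561 with an estimated correlation. No gene of the CLB2 cluster, G1/S, proteasome or Msn2/4 lists passed on its own with limma. The CLB2 cluster had a median of −0.09 (4 lower at an unadjusted p under 0.05; 4 lower adjusted over the list alone; adjusted p = 9.01e-06; adjusted p = 0.344 with an estimated correlation). The G1/S list had 0.06 (4 higher at an unadjusted p under 0.05; 0 adjusted over the list alone; adjusted p = 0.000897; adjusted p = 0.656 with an estimated correlation). The proteasome had 0.07 (9 higher and 1 lower at an unadjusted p under 0.05; 1 higher adjusted over the list alone; adjusted p = 3.8e-09; adjusted p = 0.468 with an estimated correlation). The Msn2/4 targets had 0.14 (5 higher at an unadjusted p under 0.05; 0 adjusted over the list alone; adjusted p = 1.13e-06; adjusted p = 0.656 with an estimated correlation), with −0.03 in experiment 1 and 0.29 in experiment 2. With the set block 4 genes of the CLB2 cluster were lower, and 8, 9 and 7 genes of the other lists, in this order, were higher.

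On chromosome VI in scc2-4, 2 genes rose, ULI1 and ECO1, and 0 fell (3 and 0 adjusted over the list alone), with adjusted p = 0.00521 for the list and adjusted p = 0.561 with an estimated correlation. The 10 genes beside ULI1 had a mean change of 0.01 ± 0.03 (exact two-sided permutation p = 0.459 over 1400 splits), over values from −0.10 for CDC14 to 0.35 for ECO1. In all 33 genes passed, 17 higher and 16 lower, and all 33 were among the 368 with the set block (192 higher and 176 lower). Experiment 1 alone gave 36 (19 higher and 17 lower) and experiment 2 alone 566 (249 and 317), and the set-block count fell to 245 without scc2-4 without a break 2_3. SCC2, SCC4 and MCD1 had changes of −0.07 ± 0.03, 0.02 ± 0.06 and 0.13 ± 0.09 (adjusted p = 0.658, 0.999 and 0.83), and in wild type SCC2 and SCC4 had 0.06 ± 0.04 and 0.00 ± 0.06 (adjusted p = 0.569 and 0.999). Over all genes the break effects of the genotypes, which share no arrays, correlated with r = 0.39 (0.42 with the set block; genes are not independent replicates). With the planned model 8 genes rose in both genotypes, against 0.213 for independent lists, 2 fell in both, against 0.103, and 1 went opposite ways. These counts were 78 against 15.2, 30 against 9.91, and 7 with the set block. The calls of the 2 genotypes are not independent, because both use the same estimate of the spread per gene, so the excess is not tested.

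Tested directly, the break effect differed between genotypes for 19 genes, 11 with a positive and 8 with a negative difference of scc2-4 minus wild type. HUG1 rose less in scc2-4, by a log2 difference of −1.30 ± 0.13 (SE, 27 arrays; limma adjusted p = 7.36e-07), with −1.14 in experiment 1 and −1.44 in experiment 2. PLM2 differed by −0.92 ± 0.19 (adjusted p = 0.0231), and its call ended without scc2-4 with a break 1_3 (−0.89), wild type with a break 2_1 (−0.83) or scc2-4 without a break 2_3 (−0.88). RNR3 was at −0.55 ± 0.19 (adjusted p = 0.39), with −0.20 in experiment 1 and −0.82 in experiment 2, and passed with the set block (−0.53; adjusted p = 0.0116). SMC6, of the Smc5/6 complex that acts in recombination, differed by −0.30 ± 0.06. YLL066W-B and YIR042C differed by −2.36 ± 0.10 and −1.45 ± 0.20, though another probe set of YLL066W-B was at −0.31 (set block). Of 31 DNA damage response genes 2 differed, both lower (0 higher and 6 lower adjusted over the list alone; median −0.13 in each experiment), with adjusted p = 8.95e-08 and adjusted p = 0.0936 with an estimated correlation. The list's mean difference was −0.19 ± 0.05 (two-sided residual permutation p = 0.0018; 0.0488 in experiment 1 and 0.0004 in experiment 2). The exact permutation of break labels, which assumes no break effect in either genotype, gave p = 0.132.

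Of the 11 positive differences, those of ULI1, CDC14 and ECO1 on chromosome VI were 0.60 ± 0.12, 0.57 ± 0.11 and 0.50 ± 0.08 (adjusted p = 0.0177, 0.00783 and 0.00313), and SLF1 differed by 0.78 ± 0.12, SAD1 by 0.42 ± 0.07 and GCN20, a regulator of the Gcn2 kinase, by 0.28 ± 0.05. ROG3 differed by 0.53 ± 0.11 (adjusted p = 0.0287), a call that ended in 12 of the 27 fits leaving out 1 array (adjusted p up to 0.0615) and in none with the set block. HIS2 was at 0.44 (adjusted p = 0.313; 0.00225 with the set block). The mean difference over the 10 genes beside ULI1 was 0.33 ± 0.04 (exact two-sided permutation p = 0.000328; residual permutation p = 0.0001, the smallest it can give), with 0.21 in experiment 1 (exact p = 0.025) and 0.43 in experiment 2 (exact p = 0.00857). This window was chosen after the values were seen, which these p-values do not allow for. For the difference it ranked 11 by size among the 5274. Of 117 chromosome VI genes 6 differed upward and 0 downward (12 and 1 adjusted over the list alone), with adjusted p = 3.91e-09, and adjusted p = 0.113 with an estimated correlation (0.000802 with the set block). YLR156W, YLR157W-E and ASP3-1 differed by 1.38 ± 0.28, 1.19 ± 0.21 and 0.41 ± 0.05, though another probe set of YLR157W-E, at a mean level of 3.94, was at −0.0057 (set block).

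**Figure D3:**
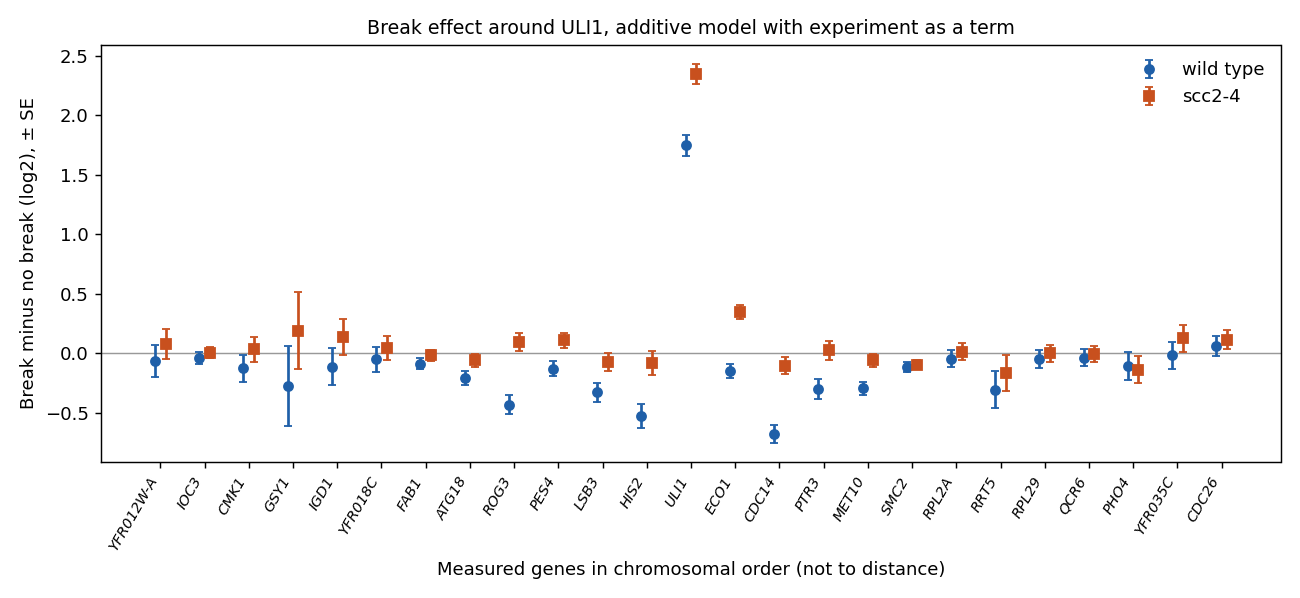
Log2 change with the break (± SE) in wild type (circles) and scc2-4 (squares) for ULI1 and the measured genes to both sides, in chromosomal order of the R64 assembly and not to distance. ULI1 rose in both genotypes (1.75 and 2.35), and the 5 genes on each side had a mean change of −0.32 in wild type and 0.01 in scc2-4.

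Among the other lists with a difference of the break effect, no M/G1 or CLB2 cluster gene passed on its own with limma. The 24 M/G1 genes had a median difference of 0.14 (2 higher at an unadjusted p under 0.05; 0 adjusted over the list alone; 3 higher with the set block), with adjusted p = 0.000192 and adjusted p = 0.754 with an estimated correlation (0.0331 with the set block). The 22 genes of the CLB2 cluster had a median of 0.08 (3 higher at an unadjusted p under 0.05; 0 adjusted over the list alone; 1 higher with the set block; adjusted p = 0.00145; adjusted p = 0.754 with an estimated correlation). Of 48 Gcn4 targets 1, ARO1, differed (2 lower adjusted over the list alone; median −0.15), with adjusted p = 4.97e-06 and adjusted p = 0.983 with an estimated correlation. ARO1 was at −0.39 ± 0.08 (adjusted p = 0.0301), and its call ended in 12 of the 27 fits leaving out 1 array (adjusted p up to 0.0685). No gene of the homologous recombination, G1/S or cytoplasmic ribosomal protein lists passed with limma either. The 20 recombination genes had a median of −0.11 (2 lower at an unadjusted p under 0.05; 0 adjusted over the list alone; adjusted p = 0.0339; adjusted p = 0.754 with an estimated correlation). The 32 G1/S genes had −0.06 (1 higher and 5 lower at an unadjusted p under 0.05; 2 lower adjusted over the list alone; adjusted p = 0.0339; adjusted p = 0.983 with an estimated correlation). The 127 ribosomal protein genes had 0.04 (0 at an unadjusted p under 0.05; 0 adjusted over the list alone; adjusted p = 0.000508; adjusted p = 0.983 with an estimated correlation). The set block gave 139 genes, 70 higher and 69 lower, which hold all 19. That count lay at 84 without scc2-4 with a break 1_3, 85 without scc2-4 without a break 2_1, 90 without scc2-4 without a break 1_1, and 91 without wild type without a break 2_1, wild type with a break 2_2 or wild type with a break 2_3. Experiment 1 alone gave 11 genes (5 higher and 6 lower) and experiment 2 alone 139 (51 higher and 88 lower). Of the 19 genes, 19 had the same sign in both experiments. The 8 lists past the threshold were no more than other splits of the arrays gave.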

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

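The tests of the 3 patterns weighed here, the splits within the parts of each set and those of experiment 1 alone, and the permutation of residuals were chosen after the results had been seen, and the rules for reading the test of the DNA damage list in experiment 1, the tests with the within-set split and the splits within its parts were revised after their outcomes, some of them repeatedly, whereas the counts of other splits within experiments were planned.

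Arrays were reassigned within experiments 100 times, the real assignment included. For the genotype comparisons 1 of 100 splits reached the 3594 genes without a break (highest other 3322) and 1 the 3356 with a break (2549). These counts do not tell genotype from processing set, because the real groups follow the sets of experiment 2 and the other splits do not. Experiment 1 alone allows 10 splits, too few for a share under 0.05, with 1569 genes without a break and 1702 with one in the real split and 0 in the highest other. For gene lists, 45 of 100 splits reached the 11 lists without a break (highest other 16) and 57 the 12 with a break (17), so chance is not excluded.

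For the break comparisons arrays were reassigned within genotype and experiment, and so within the processing sets. In each, 1 of 100 splits reached the real count, 103 genes in wild type (highest other 27), 33 in scc2-4 (6) and 19 for the difference (7). With the set block 3 splits reached the 736 genes in wild type (highest other 1363), 1 the 368 in scc2-4 (134) and 4 the 139 of the difference (1139). Few splits of this kind reached the gene counts of the break in wild type and in scc2-4. That argues against chance only if the arrays of a genotype and experiment can be exchanged. For the difference such splits assume no break effect in either genotype. They therefore do not exclude that equal break effects gave its count by chance. In wild type and for the difference, splits with more genes than the real count with the set block also point to a structure of the arrays within the sets. Splits were therefore also drawn within the parts of each set that the within-set split gives. Of 100 such splits 1 reached the count in wild type (highest other 1; 71 with the set block, which 1 reached), 1 that in scc2-4 (2; 47 with the set block, which 1 reached) and 2 that of the difference (34; 317 with the set block, which 2 reached). Whether chance is excluded under that structure stays open, because the parts were made from deviations from the means of the real groups. Made again for 100 random splits of the arrays for the difference, they were the same in 0, with a median of 21 of 27 arrays in the same part.

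For gene lists 8 of 100 splits within experiments reached the 16 lists of the break in wild type (highest other 19), 2 the 18 in scc2-4 (20) and 79 the 8 of the difference (18). Within the parts of each set 6, 5 and 70 of 100 splits did (highest other 17, 20 and 20), so chance is not excluded for these counts of lists.

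Of the 10 genes next to ULI1 5 fell with the break in wild type (8 with the set block), while in scc2-4 0 fell and ECO1 rose. The labels' descriptions put the break on the same chromosome while a characteristic names chr.iv, a conflict that the labels do not settle. In wild type 6 of 117 chromosome VI genes were higher and 22 lower at an unadjusted limma p under 0.05. On chromosome IV these were 60 and 29 of 704, and 705 of all 5434 genes changed. Such counts locate changed genes and not the break itself. A difference made by normalizing the genotypes' sets apart is argued against by experiment 1, where both genotypes lay in 1 set. There the mean difference over the 10 genes beside ULI1 was 0.21 (exact two-sided permutation p = 0.025, 400 splits; rank 24 of 5274 windows). The window was chosen after all values were seen, but in experiment 2 alone it ranked 1 for the break in wild type and 4 for the difference. A choice by the former rank does not use the arrays of experiment 1. Array structure within the sets stays open, because shifts between the parts of the within-set split carry at most 0.011 of the difference of 0.33 ± 0.04, but any parts found in every group, as centring on the group means makes them, would carry at most 0.075. A locus altered only in the wild-type strain with the break stays open (ULI1 rose in scc2-4 by 2.35 ± 0.08 but is not among the genes that fell), as does the genotype of the design, which was not tested apart from these.

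Genotype differences were larger and mostly upward in experiment 2 (SD over genes 0.606 against 0.237 in experiment 1; 69.6% of genes higher). The value distributions of the sets do not account for the size, because the ratio of these SDs was 2.33 after quantile normalization over all arrays (2.55 as deposited; 2.21 to 2.40 with 1 array left out). Whether they account for the upward excess stays open, because that normalization brings the share near 50% by construction (52.5%). Probe summaries or cultures that differed between the sets of experiment 2 cannot be told apart from genotype, since 0 of these sets hold both genotypes, so either could explain the size.

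HUG1 rose less with the break in scc2-4, and the DNA damage list had a smaller mean change there (−0.19 ± 0.05; residual permutation p = 0.0018). For HUG1 normalization of the sets apart is argued against by experiment 1 (−1.14 ± 0.18; limma adjusted p = 0.0374), while for the list the difference there was −0.17 ± 0.07, with exact p = 0.24 by permutation of break labels, a test that the break effect itself widens, and p = 0.0488 by permutation of residuals, too close to the threshold for a test chosen last, so it stays open. Array structure within the sets stays open for both, because such shifts carry at most 0.033 of the size of the HUG1 difference (−1.30 ± 0.13) and 0.0080 of that of the list, but by the same construction could carry no more than 0.244 and 0.090. Less HO in scc2-4 stays open, because only 1.90% of probe sets were brighter than HO, where differences may be compressed. The log2 difference of HO with a break was −0.026 ± 0.041 (−0.17 with arrays centred and −0.13 with quantile normalization, both past the threshold). Both settings remove offsets between the sets, and in experiment 2 the column medians were higher in scc2-4. With centring the GAL1 difference turned negative too, so these 2 HO values do not by themselves show less HO. With the set block the HO difference lay between 0.006 and 0.068 when 1 array was left out. The genotype of the design stays open as well and was not tested apart from these.

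Tests of the difference itself singled out 19 genes, with log2 differences of −2.36 for YLL066W-B (−0.31 by another probe set), −1.45 for YIR042C, −1.30 for HUG1, −0.92 for PLM2, −0.49 for RDS1, −0.39 for ARO1, −0.31 for LOT6 and −0.30 for SMC6. The positive ones were 1.38 for YLR156W, 1.19 for YLR157W-E (−0.0057 by another probe set), 0.78 for SLF1, 0.60 for ULI1, 0.57 for CDC14, 0.53 for ROG3, 0.50 for ECO1, 0.42 for SAD1, 0.41 for ASP3-1, 0.38 for DIF1 and 0.28 for GCN20. Calls ended on leaving out 1 array in 13 of 27 fits for DIF1 (adjusted p up to 0.0825), 12 for ROG3 (0.0615), 12 for ARO1 (0.0685), 9 for RDS1 (0.0690), 3 for PLM2 (0.0564) and 1 for LOT6 (0.0569, without wild type with a break 2_3 at −0.29). With the set block none of these calls ended. A response to the break is not separated here from another difference between the strains with and without it, for these genes and for the unnamed probe sets. The 8 lists had median differences of −0.13 for the DNA damage response, −0.11 for homologous recombination, −0.061 for G1/S, 0.083 for the CLB2 cluster, 0.14 for M/G1, −0.15 for Gcn4 targets, 0.038 for cytoplasmic ribosomal proteins and 0.062 for chromosome VI. None of the 8 passed with an estimated correlation in the planned model, where adjusted p ran from 0.0936 for the DNA damage response to 0.983. With the set block and an estimated correlation 2 lists passed, M/G1 and chromosome VI.

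A single array lay far from the others of its group in 21 of 604 groups tested over 151 genes, against 30.2 by chance. Each group held the arrays of both experiments, and an offset between the experiments widens its range. The count therefore does not show that outlying arrays are rarer than by chance. The gap as a share of the group's range was 0.807 for ALK1 and 0.650 for FRE3 in scc2-4 without a break 1_3. In wild type without a break 1_3 it was 0.603 for ARG1, 0.721 for MRPL32, 0.683 for NIP7, 0.612 for RPN1 and 0.744 for RRP36, and in 2_4 it was 0.611 for YLL066W-B. In scc2-4 with a break 1_1 it was 0.653 for ATP20, 0.826 for BUD4, 0.612 for MRPL1, 0.592 for MRPL40, 0.579 for MTO1, 0.578 for RDH54 and 0.676 for RSM26, and in 2_3 it was 0.604 for RNR3. In wild type with a break it was 0.629 for ARO1, 0.684 for HO and 0.676 for RAD53 in 2_1, 0.775 for PCL5 in 1_1 and 0.670 for SMC6 in 2_2.

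Among 216 probe sets without a gene name, which the comparisons did not use, 9 passed for the break in wild type, 4 for the break in scc2-4 and 4 for the difference. Under the set block 23 were higher and 11 lower for the break in wild type, 6 and 7 in scc2-4, and 3 and 5 for the difference. Between genotypes 95 were higher and 47 lower without a break (52 and 28 with the set block) and 83 and 51 with one (57 and 33). Probe set 1778286_at had a difference of −4.66, with group means of 7.22 in wild type without a break, 8.44 with one, 7.49 in scc2-4 without a break and 4.04 with one. Probe set 1774888_at had −1.11, with means of 7.66, 9.10, 6.17 and 6.45 in the same order.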

How the results depend on the processing

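The set block, the within-set split, the filter on dim genes and the repeats with the set block were chosen after the data had been seen, and the other settings were planned. A filter against probe sets of fission yeast was not run and was replaced by leaving out the dimmest 20% of genes. Where a value moved the cause was not tested, except that each experiment alone holds fewer arrays, the filter on dim genes fewer genes, and a 1.5-fold minimum adds a condition. Signal over background was not known for these values, so no bound is set on dim genes. The estimation of the array weights stopped before it reached its convergence tolerance, so the counts with them are uncertain.

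For scc2-4 against wild type without a break (3594 genes) the count was 2140 with no experiment term, 1569 in experiment 1, 2100 with the set block and 774 with a 1.5-fold minimum. With a break (3356) it was 1901, 1702 and 713 for no experiment term, experiment 1 and the 1.5-fold minimum. For the break in wild type (103) it was 248 with arrays centred, 278 with quantile normalization, 20 with no experiment term, 22 in experiment 1, 1273 in experiment 2, 405 with the compared groups alone, 276 with array weights, 736 with the set block, 2052 with the within-set split (946 higher and 1106 lower) and 11 with the 1.5-fold minimum. For the break in scc2-4 (33) it was 74, 71 and 12 for centring, quantile normalization and no experiment term, 566 in experiment 2, 423 with the compared groups alone, 1369 with array weights, 368 with the set block, 1517 with the within-set split, 10 with the 1.5-fold minimum and 15 without dim genes. For the difference (19) it was 4 with no experiment term, 11 in experiment 1, 139 in experiment 2, 71 with array weights, 139 with the set block, 682 with the within-set split, 8 with the 1.5-fold minimum and 11 without dim genes.

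Counts with the trended robust variance model and with all probe sets stayed within 1.5 times those of the planned model in all 5 comparisons. Leaving out 1 array gave 3261 to 3808 and 2900 to 3566 genes for the genotype comparisons without and with a break, 24 to 40 for the break in scc2-4 and 14 to 22 for the difference. It gave 74 (without wild type without a break 2_1) to 165 genes (without 1_2 of that group) for the break in wild type. With the set block it gave 245 (without scc2-4 without a break 2_3) to 412 (without 2_2 of that group) for the break in scc2-4, and 84 (without scc2-4 with a break 1_3) to 178 (without wild type without a break 2_4) for the difference. The latter count also moved to 85 without scc2-4 without a break 2_1, 90 without 1_1 of that group, and 91 without wild type without a break 2_1 or wild type with a break 2_2 or 2_3. The correlation of the break effect in scc2-4 between experiments (r = 0.22 over genes) ran from 0.03 without scc2-4 with a break 1_1 to 0.39, and that in wild type (0.42) from 0.08 without wild type without a break 1_3 to 0.60.

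With the planned model the lists past the threshold numbered 11 and 12 for the genotype comparisons, 16 and 18 for the break in wild type and scc2-4, and 8 for the difference. With an estimated correlation 1, 0, 3, 0 and 0 passed, and 1, 1, 4, 0 and 2 with the set block as well. Counts with fry were 30, 31, 5, 3 and 1.

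Of the genes chosen by the naming rule, 43 of 62, 43 of 56, 41 of 49, 32 of 46 and 29 of 33 kept their direction and their side of the threshold with the set block, in the order of the comparisons above. In experiment 1 alone 37, 43, 29, 33 and 19 did, and with quantile normalization 59, 51, 45, 43 and 28. Genes with a call in either fit turned direction in these settings in the genotype comparisons and not in the break comparisons. Without a break this was so in experiment 1 for ALD3 (0.15), MCD1 (−0.035), NIP7 (−0.048), RNR3 (−0.15), RRP36 (−0.050) and SCC4 (0.042), with centring and quantile normalization for GAL1 (−0.11 and −0.056), with the set block for NIP7 (−0.023), RRP36 (−0.021) and SCC4 (0.0084), and with the within-set split for NIP7 (−0.033), RRP36 (−0.016) and SCC4 (0.0053). HO passed without a break with the within-set split (0.097). With a break a turn was seen for GAL1 with centring (−0.11) and for MCD1 with the within-set split (−0.14). Values without a call in either fit turned sign as well. With a break these were MCD1 (−0.14), SCC4 (0.017), HO (0.022) and GAL1 (−0.027) with the set block. For the break they included HO in scc2-4 in experiment 2 (0.0063), SCC4 for the difference in experiment 1 (−0.058) and, with 1 array left out, HO and SCC4 in wild type (to −0.0099 without 1_1 and −0.030 without 1_3, both without a break) and SCC4 in scc2-4 (−0.011 without 2_3 without a break).

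The replicate numbers of the labels were not taken to pair the arrays, because that asked for r over 0.1 in every pair with the same number. Deviations of arrays with the same number correlated with a median r of 0.31 (−0.67 to 0.77 over 39 pairs), and 14 of the 39 lay at or below 0.1, against a median of −0.16 for different numbers. Of 27 arrays 11 correlated best with their own number. The parts of the sets followed the numbers in part, with 8 of 8 arrays of number 1 in the first, all 8 of number 3 and 3 of number 4 in the second, and number 2 divided 5 and 3. The replicate block gave 3479, 3106, 99, 30 and 14 genes and 11, 12, 13, 18 and 8 lists in the order above, and turned no direction of a gene with a call. Of the genes chosen by the naming rule 2 of 49 lost their call for the break in wild type. For the break in scc2-4 4 of 46 did, and for the difference 5 of 33.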

Other observations

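Many meiotic genes were lower in scc2-4 without a break. Of 47 genes of meiosis and sporulation 24 fell and 7 rose (24 and 7 adjusted over the list alone; median −0.21), and 17 fell and 5 rose with the set block. HOP1, of the meiotic chromosome axis, had a log2 change of −1.0 ± 0.06 (SE, 7 against 7 arrays; −0.86 with the set block), REC102, of meiotic break formation, of −0.92 ± 0.10 (−0.58) and the sporulation gene SPO74 of −0.85 ± 0.08 (−0.65). SPO73 was at 0.82 ± 0.23 over all arrays and at −0.10 with the set block (limma adjusted p = 0.429). The list median was −0.13 in experiment 1 and −0.26 in experiment 2, with adjusted p = 2.44e-07 and adjusted p = 0.0183 with an estimated correlation (0.256 with the set block). With a break 25 fell and 9 rose (25 and 9 adjusted over the list alone), HOP1 among them at −0.79 ± 0.06, with adjusted p = 9.19e-06 and adjusted p = 0.0701 with an estimated correlation. The set block left 15 lower and 7 higher there, and the list did not pass (adjusted p = 0.0949).

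Many genes of the cytoplasmic ribosome and of ergosterol synthesis were higher with the planned model and not with the set block. With the planned model 2532 of all 5434 genes were higher, with a median of 0.13 over all genes. The rise of the ribosomal protein genes is not told apart from this general shift. Of 127 cytoplasmic ribosomal protein genes 66 were higher and 1 lower in scc2-4 without a break over all arrays (50 and 1 adjusted over the list alone; median 0.13), but 0 were higher and 29 lower with the set block (0 and 19 adjusted over the list alone; median −0.06). RPS10A, of the small subunit, was at 0.50 ± 0.14 and at 0.00 with the set block (adjusted p = 0.994). The list gave adjusted p = 0.122 over all arrays, and 0.000383 with the set block (adjusted p = 0.838 with an estimated correlation). Of 27 ergosterol synthesis genes 22 were higher and 1 lower over all arrays (23 and 1 adjusted over the list alone), and 1 was higher and 4 lower with the set block, with adjusted p = 0.127 and 0.465. UPC2, the sterol-sensing activator, was lower in both, at −0.86 ± 0.15 and −0.51, whereas ERG28 was at 0.87 ± 0.20 and 0.11 (adjusted p = 0.438 with the set block).

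The chaperone gene SSA4 was lower in scc2-4 with a break at −0.76 ± 0.12 (−0.47 with the set block), and the zinc regulator ZAP1 was higher at 0.60 ± 0.07 (0.48). Mean levels over the groups and experiments ran from 6.03 to 6.71 for the a-factor gene MFA1, from 5.37 to 5.91 for the receptor gene STE2 and from 4.99 to 5.94 for the receptor gene STE3, while column medians were 9.76 or more.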
